A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

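Small RNA libraries were made from total RNA of the head kidney of 6 female rainbow trout, extracted with TRIzol, with the NEBNext small RNA kit for Illumina, per the labels' protocols. The series' design text gives 3 fish at 18 °C and 3 at 24 °C, and the length of the heat treatment is not given in the sources used here. The read counts per miRNA were deposited by the authors as whole numbers for 1381 rows, 392 with Atlantic salmon (ssa) names and 989 numbered as predictions (written novel_ and a number), per the file headers. The TPM values deposited by the authors equal each count divided by its library's sum over all rows, scaled to a common total (largest difference 2.33e-10), so they hold no length term and no further information. Bowtie is named in the submitters' processing notes. Its version, the counting of reads that match several miRNAs, the length filter and the genome build are not given in the sources used here. The table holds names without sequences or coordinates, so no genomic positions are given and predicted rows cannot be tied to known families. Reads that match near-identical copies, such as paralogs kept after the salmonid genome duplication, may be split or shared between rows in the authors' counting. Library totals ran from 3753036 to 5156793 counts, and a floor of 3 counts was worth 0.582 to 0.799 CPM. Binomial and Poisson intervals and floors cover counting error only, while intervals of fold changes, slopes and log ratios come from the spread between fish.

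Libraries were assigned to groups by their titles and the design text, and the replicate is the fish. No pair of libraries agreed within sampling noise (chi-square per degree of freedom from 117 to 344 over all pairs). Counts were tested with edgeR 4.0.16 in R 4.3.3: rows were kept by filterByExpr (minimum count 10, minimum total 15), which left 537 rows, libraries were scaled by TMM over the kept rows with totals over all rows, and a robust quasi-likelihood fit compared heat with control. Fold changes are 24 °C over 18 °C, standard errors are the log2 fold change divided by the root of the F statistic, and p-values were adjusted by Benjamini-Hochberg over the 537 rows with a threshold of 0.05. CPM values in the text are TMM-scaled. The biological coefficient of variation over all rows was 42.2%. Lists of miRNA families were tested with limma 3.58.1 (camera, preset correlation 0.01), beside camera with an estimated correlation and fry, with adjustment over the 14 lists of at least 3 kept rows. The families were matched by the number in the name, and some families stand in more than 1 list. The ratio of 5p to 3p counts was tested with limma on log2 ratios with 0.5 added to each count, for precursors with a mean of at least 10 counts per arm. Shares of counts were compared by two-sided exact permutation tests, which cannot go below 0.1 with 3 against 3.

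The lists of families and the rule for the miRNAs to name were set before the data were examined: those that passed with groups fully apart and a mean of at least 10 CPM (up to 12 annotated and 3 predicted per direction), the 5 annotated rows of smallest p in a direction where fewer than 5 passed, the 5 most abundant rows, up to 4 rows per list and the 5 precursors of smallest p. On simulated counts with the means and spread of these libraries and 200 changed rows among 537, the fit made no call in the wrong direction, and 2.4% of its calls were unchanged rows. A list of 16 rows shifted 4-fold was called, with none of 12 unrelated lists called. The simulated rows were drawn independently, so the list test was not checked on rows that vary together. The arm test found 10 of 10 ratios changed 4-fold among 79 with 0 false calls. Alternatives were other scalings (DESeq2 size factors, library totals, upper quartile), DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 10), other filters, a fit that is not robust, summed copies, annotated rows only, a replicate block, other thresholds and each library left out in turn. The edgeR fit of the other version, a muscle index as a covariate, the muscle list without miR-499 and the share of the same 10 miRNAs without each library were added after seeing the data. Figures were drawn with matplotlib 3.10.9.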

Results

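Small RNA from the head kidney, the main blood-forming and immune organ of teleost fish, was sequenced from 6 female rainbow trout (Oncorhynchus mykiss) aged 1 year. There were 3 control fish held at 18 °C and 3 heat-treated fish held at 24 °C, with 1 library per fish. The comparison asks which microRNAs (miRNAs, short RNAs that repress target mRNAs) differ in abundance in this organ under heat stress. The table held 1381 miRNAs, of which 392 carried Atlantic salmon miRNA names and 989 were numbered predictions with no family name. The control libraries held 5063549, 3753036 and 4746187 counts and the heat libraries 5156793, 4511972 and 4289895. Of the 1381 miRNAs, 537 had enough counts to be tested (283 annotated, 254 predicted), and these took 99.9% of all counts.

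The most abundant miRNA was miR-126-3p, which is known from vessel endothelium, at 88932 ± 13544 CPM (TMM-scaled counts set to a common library total; SD, n = 3) at 18 °C and 94334 ± 7675 CPM (n = 3) at 24 °C. It was followed by miR-21b-5p and miR-146a-5p, whose families are tied to inflammatory signalling, and by miR-100a-5p and miR-10a-5p, the latter encoded in a Hox cluster. The log2 fold changes of these 5 lay between -0.21 ± 0.20 (SE) for miR-146a-5p and 0.11 ± 0.17 for miR-21b-5p, and none passed the test. The 10 most abundant miRNAs took 56.2% ± 0.255 of the counts at 18 °C and 53.7% ± 1.61 at 24 °C (SD, n = 3 each). All 3 heat libraries lay below all 3 control libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows), and the difference was -2.52 percentage points. It was -0.80 for the 5 most abundant (exact permutation p = 0.8) and -0.74 for the 20 most abundant (exact permutation p = 0.5). Without heat replicate 3 the difference for the 10 most abundant was -1.59 percentage points with the same 10 miRNAs, and -0.69 when the 10 were chosen again from the other 5 libraries. Predicted miRNAs took 4.996% ± 0.553 of the counts at 18 °C and 5.12% ± 0.528 at 24 °C, a difference well inside the spread between fish (exact permutation p = 0.8). Its sign turned without control replicate 3 (-0.16 percentage points) or heat replicate 2 (-0.18). Among single libraries the share of the 10 most abundant ran from 51.8% in heat replicate 3 (exact binomial 95% interval 51.76% to 51.86%) to 56.4% in control replicate 3 (56.33% to 56.42%), intervals that cover counting error only.

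A single miRNA, miR-499a-5p, passed the test between the temperatures. It is encoded within a myosin heavy chain gene and is known from heart and slow muscle. Its abundance rose from 162 ± 35.9 CPM at 18 °C to 935 ± 181.1 CPM at 24 °C (SD, n = 3 each), which is 5.78-fold. Each heat library (726.8, 1029 and 1051 CPM) lay above each control library (150.3, 202 and 133.4 CPM). The log2 fold change was 2.53 ± 0.25 (SE; 95% interval 1.93 to 3.13; edgeR quasi-likelihood adjusted p = 0.0092). The row of the related miR-499b-5p stood at 180 ± 87.6 CPM at 18 °C and 114 ± 70.0 CPM at 24 °C, and its log2 fold change of -0.66 ± 0.61 did not pass (edgeR adjusted p = 0.84). With 1 fish fewer, the edgeR adjusted p of miR-499a-5p was 0.15 without control replicate 1, 0.086 without control replicate 3 and 0.077 without heat replicate 2, while its log2 fold change stayed between 2.40 and 2.68.

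**Figure D1:**
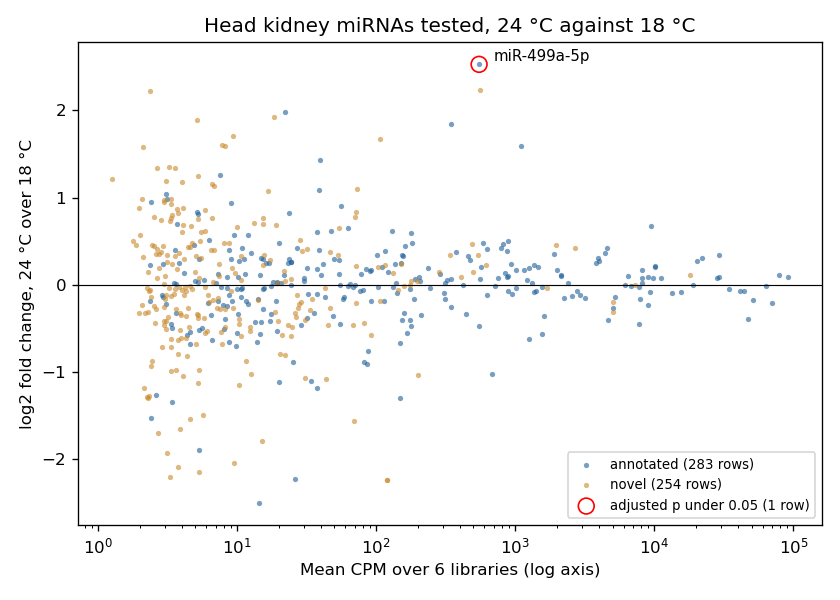
Log2 fold change at 24 °C over 18 °C (vertical axis) against mean CPM over the 6 libraries (log horizontal axis) for the 283 annotated (blue) and 254 predicted (orange) miRNAs tested. The circled miR-499a-5p, at 2.53, is the 1 miRNA past the adjusted p threshold of 0.05.

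Among the other annotated miRNAs, those with the smallest p-values on the higher side at 24 °C did not pass the adjusted threshold. miR-7132a-3p had a log2 fold change of 1.09 ± 0.30 (24.7 ± 2.80 CPM at 18 °C, 52.7 ± 13.3 CPM at 24 °C, n = 3 each), and miR-730a-5p one of 1.26 ± 0.36 at only 4.44 and 10.6 CPM. miR-146d-5p, a member of the miR-146 family known to restrain innate immune signalling, had 7269 ± 1501 CPM at 18 °C and 11629 ± 2650 CPM at 24 °C (log2 fold change 0.68 ± 0.23). miR-22b-5p had a log2 fold change of 0.62 ± 0.24. On the lower side, miR-458-3p had 918 ± 189 CPM at 18 °C and 450 ± 54.2 CPM at 24 °C, a log2 fold change of -1.03 ± 0.21. miR-7132b-5p had 1863 ± 50.3 and 1257 ± 69.9 CPM (log2 fold change -0.57 ± 0.14). The rows of miR-19c-4-5p (-1.54 ± 0.47), miR-462b-3p (-0.89 ± 0.29) and let-7b-3p (-1.11 ± 0.40) also had negative log2 fold changes. Of these, miR-19c-4-5p stood at only 3.54 CPM at 18 °C and 1.23 CPM at 24 °C. The edgeR adjusted p of these 9 miRNAs lay between 0.32 and 0.63.

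No miRNA passed edgeR's test on the lower side with all 6 libraries, where 17 had an unadjusted p under 0.05, against 18 on the higher side and 26.9 expected by chance over both. DESeq2 called 2 higher (miR-499a-5p and miR-7132a-3p) and 3 lower (miR-458-3p, miR-7132b-5p and novel_242). The last was chosen after its values were seen; it had 104 ± 34.02 CPM at 18 °C and 35.2 ± 1.87 CPM at 24 °C. Without control replicate 2, edgeR called novel_959 lower (log2 fold change -5.17, adjusted p = 0.046), likewise named after its values were seen. This row was not among the 537 tested with all 6 libraries. The count filter was run again without that library and let it in. In simulated data with these libraries' spread, 200 of 537 miRNAs were changed at once. The edgeR test found 16.4% of 2-fold changes, 76.1% of 4-fold changes and 90.9% of 8-fold changes. Most 2-fold changes were therefore not detectable with 3 fish per group. Where fewer miRNAs change, the adjustment is stricter and these shares are expected to be lower.

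The miRNAs were then grouped into lists of families, of which 14 had at least 3 tested members. The muscle list (miR-1, miR-133, miR-206, miR-208 and miR-499 families) had the highest median log2 fold change, 1.64 over 6 tested members. Apart from miR-499a-5p, the 1 member that passed both over all miRNAs and adjusted over the list alone, these were miR-1-3p, the most abundant miRNA of striated muscle (149 ± 111 CPM at 18 °C, 536 ± 444 CPM at 24 °C, log2 fold change 1.85 ± 0.74), miR-206-3p (1.43 ± 0.73), miR-133a-3p (1.99 ± 0.84) and both arms of miR-499b. miR-133a-3p was named after its values were seen. As a set the list rose against the other miRNAs (limma camera with a preset correlation of 0.01, adjusted p = 0.00015), a call lost with an estimated correlation (adjusted p = 0.34). Heat replicate 3 held the most miR-1-3p, miR-206-3p and miR-133a-3p (1037, 111 and 72.7 CPM), and also the most of the red cell miRNA miR-144-5p (3015 CPM). The other arm, miR-144-3p, was instead highest in control replicate 1 (40.4 CPM, against 36.8 CPM in heat replicate 3). Without heat replicate 3 the muscle list median was 0.65, with a camera adjusted p of 0.0099.

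**Figure D2:**
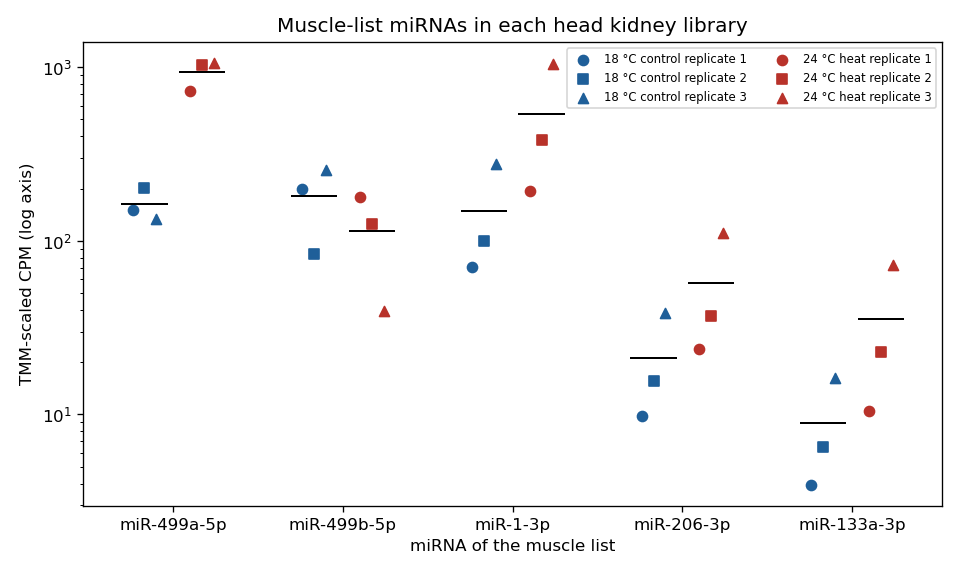
TMM-scaled CPM (log vertical axis) of 5 muscle-list miRNAs in the 3 control (blue) and 3 heat (red) libraries; marker shapes give the replicate number and bars the group means. All heat values of miR-499a-5p, from 726.8 to 1051 CPM, lie above its control values, while the groups overlap for miR-499b-5p, miR-1-3p, miR-206-3p and miR-133a-3p.

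The epithelial list (miR-200, miR-141, miR-429, miR-203 and miR-205 families) had the lowest median log2 fold change of the 14 lists, -0.91 over 7 tested members, and all 7 estimates were negative. No member passed the test, either over all miRNAs or adjusted over the list alone. miR-200b-3p stood at 209 ± 143.5 CPM at 18 °C and 84.8 ± 28.7 CPM at 24 °C (log2 fold change -1.30 ± 0.68), and miR-200a-3p at 112 ± 70.1 and 59.5 ± 29.9 CPM (-0.91 ± 0.67). miR-203a-3p had a log2 fold change of -0.48 ± 0.24 and miR-205a-5p one of -0.06 ± 0.33. As a set the list fell (camera adjusted p = 0.042), and the call was lost in camera with an estimated correlation (adjusted p = 0.34). That estimate, 0.0049, was below the preset 0.01, so correlation between members does not account for this loss. The call was also lost without control replicate 1 (adjusted p = 0.40), control replicate 3 (0.37), heat replicate 1 (0.18) or heat replicate 2 (0.054). Control replicate 2, with 43.3 CPM of miR-200b-3p, lay below every heat library, and without it the median was -1.56 (adjusted p = 3.99e-05). Without heat replicate 3 the median was -1.37 (adjusted p = 0.0099).

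The myeloid and lymphoid lists did not pass as sets, with a camera adjusted p of 0.90 for both the myeloid and the lymphoid list. In the myeloid and inflammation list (16 tested members, none passed), miR-21b-5p had 75332 ± 10238 and 81089 ± 15607 CPM at 18 and 24 °C, miR-21a-5p had 18960 ± 2644 and 18907 ± 1275 CPM, and miR-146a-5p had 75575 ± 7465 and 65125 ± 17678 CPM. In the lymphoid list (16 members, none passed), miR-181a-5p had a log2 fold change of -0.04 ± 0.19 and miR-181c-5p of 0.09 ± 0.15. miR-150-5p, known from mature lymphocytes, had 683 ± 102 and 944 ± 136 CPM (0.47 ± 0.20), and miR-29b-3p had a log2 fold change of 0.42 ± 0.23. For the myeloid list the median (0.04) and the direction of camera were positive and the mean (-0.05) negative, while the lymphoid list had a positive median (0.01) with a negative mean (-0.01) and direction of camera. The erythroid list held 2 tested members, both arms of miR-144, a miRNA of red blood cell precursors, too few for a set test. miR-144-5p had 549 ± 264 CPM at 18 °C and 1656 ± 1316 CPM at 24 °C, with 3015 CPM in heat replicate 3 (log2 fold change 1.59 ± 0.70, not passed), and miR-144-3p had 29.2 ± 10.4 and 31.0 ± 11.7 CPM. The endothelial miR-126-5p had a log2 fold change of -0.15 ± 0.24.

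The interferon list holds miR-462 and miR-731, a teleost pair induced by virus and interferon. Its abundant members differed by less than the spread between fish: miR-462a-5p had 10922 ± 627 and 11487 ± 1110 CPM, miR-462b-5p 7835 ± 489 and 7671 ± 486.4 CPM, and miR-731-5p 6174 ± 851 and 6181 ± 362 CPM at 18 and 24 °C, and miR-731-3p had a log2 fold change of 0.04 ± 0.20. The rarer miR-462b-3p had a log2 fold change of -0.89 ± 0.29, with all 3 heat libraries below all 3 control libraries, and did not pass. The list median was -0.001 and its mean -0.14. The list of teleost families (20 tested members) had a median of -0.001, and miR-458-3p was the 1 member that passed adjusted over the list alone, on the lower side. There miR-2188-5p had a log2 fold change of 0.50 ± 0.26. In the hypoxia and stress list none of 20 members passed, and miR-125a-5p (0.10 ± 0.20), miR-125b-5p (0.22 ± 0.21), miR-27c-3p (-0.07 ± 0.24) and miR-27b-3p (0.09 ± 0.27) had small log2 fold changes. Its median (0.08) and direction of camera were positive and its mean (-0.03) negative. These 3 lists had camera adjusted p-values of 0.72, 0.87 and 0.95.

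None of the 26 tested members of the miR-17/92 clusters, which are tied to cell proliferation, passed. Their median log2 fold change was 0.09, with miR-92a-3p at 0.31 ± 0.27, miR-20a-5p at 0.27 ± 0.26, miR-25-3p at 0.08 ± 0.23 and miR-19a-3p at 0.08 ± 0.29. Of 18 let-7 members none passed, and let-7e-5p (44971 ± 5000 and 42911 ± 2483 CPM) and let-7a-5p (27450 ± 2574 and 28903 ± 3101 CPM) had log2 fold changes of -0.07 ± 0.13 and 0.07 ± 0.14. In the kidney tubule and gut list (19 members, none passed) miR-30b-5p had a log2 fold change of -0.08 ± 0.12 and miR-30d-5p of -0.45 ± 0.24. The Hox cluster list (6 members) had a median of -0.16 and a negative direction of camera but a mean of 0.12, with miR-10a-5p at -0.18 ± 0.14. The mesenchymal list (12 members) had a median of -0.07, with miR-143-3p of smooth muscle and fibroblasts at 53521 ± 12413 and 40803 ± 11919 CPM. In the neural and endocrine list 14 of 16 members had a positive estimate and none passed, and miR-7a-5p had a log2 fold change of 0.08 ± 0.12 and miR-375-3p of 0.19 ± 0.31. The miR-183 cluster (3 members) had a median of 0.16. The camera adjusted p of these 7 lists lay between 0.70 and 0.87. The liver miRNA miR-122-5p was scarce, at 55.0 ± 43.0 and 42.6 ± 27.4 CPM, and the early embryo family miR-430 had no row that could be tested.

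**Figure D3:**
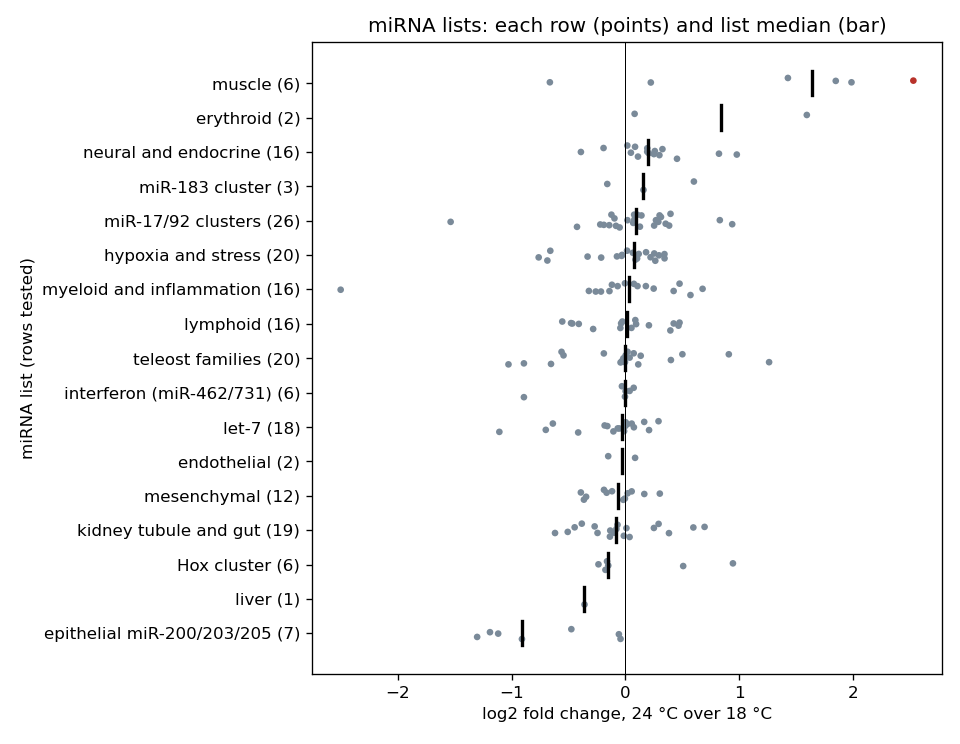
Log2 fold change at 24 °C over 18 °C (horizontal axis) of each tested member of the miRNA lists (points; red marks adjusted p under 0.05) with the list median (bar); the number of tested members follows each name. The muscle median lies at 1.64 and the epithelial median at -0.91, and the other lists of at least 3 members have medians between -0.16 and 0.20.

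The balance between the arms of a hairpin was compared as the log2 ratio of 5p to 3p counts for 79 precursors with both arms counted. No ratio passed the test (limma, smallest adjusted p = 0.067), and 7 had an unadjusted p under 0.05. The smallest p-values belonged to let-7b, whose 5p to 3p log2 ratio was 5.68 ± 0.024 at 18 °C and 6.86 ± 0.320 at 24 °C (SD, n = 3 each; limma adjusted p = 0.067), and to miR-7132a, at 6.001 ± 0.183 and 4.88 ± 0.201 (limma adjusted p = 0.067). For both precursors the 3 heat libraries lay clear of the 3 control libraries. Both passed when precursors had to hold a mean of at least 50 counts per arm, which left 53 to test (limma adjusted p = 0.019). The changes of miR-338a (-1.27 ± 0.42, SE), miR-462b (0.88 ± 0.29) and miR-1338 (-0.81 ± 0.30) did not pass.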

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

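The tests with the muscle covariate, the other edgeR version, the muscle list without miR-499 and the same 10 miRNAs without a library were chosen after the results were seen. The count of miRNAs higher at 24 °C was 1 in every planned setting except DESeq2 (2), the replicate block (0) and the fits that left out a library (0 to 1), and it was 0 with the muscle covariate. miR-499a-5p passed in 16 of 20 settings, that covariate aside, with a log2 fold change from 2.40 to 2.68, and its adjusted p was 0.079 in edgeR under the block (range 7.95e-19 in DESeq2 to 0.15 in edgeR). The count of miRNAs lower was 0 except with DESeq2 (3) and without control replicate 2 (range 0 to 1). That call was novel_959, named after its values were seen, a row that the count filter had left out of the main fit. Lists moved numbered 2, but 0 with an estimated correlation, 0 with fry, 1 with the replicate block and 1 to 2 without a library; fry's smallest adjusted p was 0.50. The muscle list without miR-499 had a median of 1.85 (camera adjusted p = 0.029; 0.93 with an estimated correlation). Arm ratios numbered 0, but 2 with at least 50 counts per arm, where fewer precursors were tested. The difference in the share of predicted miRNAs ran from -0.18 to 0.39 percentage points without a library, and that of the 10 most abundant from -3.03 to -0.69 when the 10 were chosen again, or -3.03 to -1.59 for the same 10, against -0.80 for the 5 and -0.74 for the 20 most abundant. Samples of the same number did not deviate together (correlations of -0.06, -0.18 and -0.15). No sample deviated most closely with its own number in the other group. These values gave no sign that the numbers pair the fish, but with 1 pair per number a modest shared effect is not excluded. The block leaves fewer residual degrees of freedom. Of 1298 values of named miRNAs under the alternatives, 83 had the other sign, all of miRNAs at or under 0.364 in size that passed in neither fit, and 0 reversed a call. The cause of the differences between DESeq2 and edgeR was not tested. Rare miRNAs were measured less precisely, and counting error was not separated from the spread between fish: the median SE was 0.50 for the 221 miRNAs under 10 CPM and 0.19 at 1000 CPM or more.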

Other observations

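The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the libraries. The miRNAs miR-204-5p, miR-146b-5p, miR-202-3p, miR-7132a-5p, miR-203b-3p, miR-205b-5p, miR-499a-3p and novel_121 were also chosen after their values were seen.

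Most abundant miRNAs of the head kidney differed by less than 2-fold. Of 74 miRNAs with a mean of at least 1000 CPM, 65 had a 95% interval of the fold change inside 2-fold either way, against 169 of all 537 tested, and none passed the test. The ends of this range were miR-144-5p at 1.59 ± 0.70 and miR-204-5p, known from kidney and eye epithelium, at -0.62 ± 0.29. Of the miR-146 family, none of which passed, miR-146d-5p had a log2 fold change of 0.68 ± 0.23, miR-146a-5p of -0.21 ± 0.20 and miR-146b-5p of -2.50 ± 1.00, the last resting on control replicate 2 (60.5 CPM against 3.10 to 7.74 CPM in the other 5 libraries). The gonad miRNA miR-202-3p ranged from 12.2 to 85.3 CPM in the control and from 2.51 to 19.8 CPM in the heat libraries. Of the miR-7132a hairpin, whose arm ratio did not pass, the 3p arm had a log2 fold change of 1.09 ± 0.30 and the 5p arm of -0.03 ± 0.20.

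The rise of miR-499a-5p raises the question of muscle carried over in dissection. Muscle of one makeup would bring miR-499a-5p and the miRNAs miR-1-3p, miR-206-3p and miR-133a-3p in a fixed proportion, but within groups miR-499a-5p followed their mean log2 CPM with a slope of 0.061 (95% interval -0.42 to 0.54, a slope of 1 being a fixed proportion), and with this mean as a covariate its log2 fold change was 2.42 ± 0.37 (edgeR adjusted p = 0.24, with a larger standard error and 1 residual degree of freedom fewer). Reads moved from the miR-499b-5p row are also argued against, since the summed rows had a log2 fold change of 1.60 (95% interval 1.12 to 2.09). The choice among scalings does not account for the rise, since the lowest value over 3 other scalings was 2.46. The check was mild: these scalings put the median of all tested miRNAs between -0.063 and 0.0004, against 0.002 in the main fit. The opposite arm, miR-499a-3p, had 3 reads over the control and 23 over the heat libraries, 7.47 times as many per scaled read. The exact Poisson interval was 2.26 to 38.9 for counting error only, and the exact permutation p over libraries was 0.1. More of the hairpin in the heat libraries would give this, whether from carried-over tissue or from head kidney cells. Tissue rich in miR-499a but poor in the other muscle miRNAs, and a response to heat in head kidney cells, both stay open and were not tested.

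The other muscle miRNAs shared a common level that varied over the 6 libraries with an SD of 1.34 on the log2 scale and was highest in heat replicate 3, as was the red cell miRNA miR-144-5p (3015 CPM). miR-144-3p, from the same hairpin, was instead highest in control replicate 1 (40.4 CPM, against 36.8 CPM in heat replicate 3). The log2 ratio of miR-206-3p to miR-1-3p changed by -0.43 between the groups (95% interval of a linear model -0.76 to -0.10, exact permutation p = 0.1, the smallest possible). All 3 heat libraries lay below all 3 control libraries. This argues only weakly against a muscle source of one makeup for this pair. The SD of the ratio over the libraries was 0.27, small beside the 1.34 of the common level. The log2 ratio of miR-133a-3p to miR-1-3p changed by -0.024 (-0.33 to 0.28; exact permutation p = 0.9), with an SD of 0.12 over the libraries, which is consistent with one muscle source in differing amounts for that pair. Muscle of differing makeup and shared control of these miRNAs in head kidney cells stay open and were not tested.

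The lower level of the epithelial list could come from a differing amount of epithelium in the dissected pieces, in which case its members should fall alike. The log2 ratio of miR-205a-5p to miR-200b-3p changed by 0.86 between the groups, with a 95% interval of -2.65 to 4.38. At this spread the group change cannot tell this explanation from a change in part of the list. Among the control fish alone the ratio ran from -2.26 (replicate 3) to 1.30 (replicate 2), and it was 1.05 in heat replicate 1. This argues against a single epithelial source of fixed makeup for this pair. miR-200a-3p, however, was lowest in the same libraries as miR-200b-3p (30.7 CPM in control replicate 2, 26.0 CPM in heat replicate 1). In control replicate 2, miR-203b-3p (21.8 CPM) and miR-205b-5p (10.5 CPM) lay low together with miR-200b-3p, while miR-203a-3p (210.4 CPM) and miR-205a-5p (107 CPM) did not.

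Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 1 miRNA on the higher side, where the highest of the other splits gave 0, and 1 of the 10 splits, the real one, reached that count. It gave 0 on the lower side, a count that any split reaches, so this comparison cannot decide anything, and the highest other value was 0. It gave 2 lists, which 2 of the 10 splits reached, the other one pairing control replicates 1 and 3 with heat replicate 3. Control replicates 1 and 2 with heat replicate 1 gave 1 list, as did the same controls with heat replicate 2. Control replicates 1 and 3 with heat replicate 2 gave 1 list, as did control replicate 1 with heat replicates 1 and 3. Lists were thus also called under wrong groupings. The real split gave 0 arm ratios, again a count that any split reaches, and the highest other value was 1.

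Among 254 predicted miRNAs, novel_121 had the highest positive Pearson correlation with the red cell miRNA miR-144-5p over the 6 libraries (Pearson r = 0.957, exact permutation p = 0.0042, adjusted p = 0.35; Spearman rho = 0.943, exact permutation p = 0.017, adjusted p = 0.53). Without the 2 libraries farthest from the median of miR-144-5p, r was 0.864. Inverse relations were as strong, with r = -0.960 (adjusted p = 0.35, from exact permutations) for both novel_323 and novel_1505, also chosen after their values were seen. With 6 libraries the exact permutation p of Pearson r cannot go below 0.0014. That is too large for a single miRNA among 254 to pass the adjustment. A shared cell source failed this correction, which therefore could not decide it, and stays a hypothesis that may be chance.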
